A study of Homo sapiens with 4 samples.

How the data were processed

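Bulk RNA sequencing was done on 4 libraries, 1 per group, from engineered prostate cancer tissues at day 15: PC-3 monoculture, LNCaP monoculture, PC-3 coculture and LNCaP coculture. The cocultures held PC-3 or LNCaP cells and BJ-5ta fibroblasts at a ratio of 5 to 1. The growth protocol in the labels describes PC-3 tissues, so the medium of the LNCaP tissues was not known. The series description gives RNA from more than 2 tissues, without saying whether it was pooled before library preparation or libraries were merged afterwards, and with 1 column per group the spread between tissues could not be seen. Total RNA came from a QIAshredder and RNeasy extraction and went into TruSeq RNA v2 libraries, per the labels. That kit does not mark the strand, so the source of reads is uncertain where genes overlap, such as TALAM1 and MALAT1, as it is for read-through genes (TEN1-CDK3, RBM14-RBM4, ARMCX5-GPRASP2) and for families with near-identical copies (PCDHGA6, BOLA2B and the ribosomal protein genes).

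The deposited table holds estimated counts per gene symbol, not scaled to a common total, for 17791 genes. FastQC, STAR and Partek and the build hg38 are named in the submitters' processing notes; their roles, versions, annotation and filters were not given in the sources used here. Between 33.7% and 34.1% of values in a library were not whole, as estimated counts can be, and all were rounded to whole numbers before use. The table names a chromosome for each gene but no position, so positions came from RefSeq on GRCh38.p14, which held 17147 of the symbols. All 4 sample columns were used. The table has 0 of the 13 mitochondrially encoded transcripts, so this list could not be measured, and 20 genes were at 0 in all libraries.

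Total counts were 15865690 (PC-3 monoculture), 15860981 (LNCaP monoculture), 15687894 (PC-3 coculture) and 15520243 (LNCaP coculture), with 16904, 16360, 17064 and 16661 genes at 1 count or more. A count of 0 allows up to 3 counts, or 0.189 CPM in either monoculture, 0.191 CPM in the PC-3 coculture and 0.193 CPM in the LNCaP coculture. Ribosomal RNA genes took 0.751%, 1.46%, 2.16% and 1.23% of counts in the same order. The 20 most abundant genes took 5.64%, 7.65%, 5.82% and 7.37%.

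Counts were scaled with TMM factors (edgeR 4.0.16 in R 4.3.3), which lay between 0.996 and 1.006, to CPM, counts per 1000000 counts. Log2 folds used a prior count of 2. Folds given without a log are ratios of scaled counts with an exact 95% interval from the conditional binomial distribution of the 2 counts. A gene at 0 in 1 library is given as at least the fold against 3 counts in that library, and no fold is given where both libraries had 3 counts or fewer. These intervals and floors cover counting error only, because reads without molecular identifiers are not independent molecules and no group had a replicate. For the same reason no test of any difference between groups was run. Genes were counted as at least 2-fold higher or lower by their log2 fold among genes with at least 1 CPM in 1 of the 2 libraries. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

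The 4 comparisons were each coculture against its monoculture, and LNCaP against PC-3 in monoculture and in coculture. The log2 folds of the cocultures were also subtracted gene by gene, LNCaP minus PC-3, with a 95% interval from the delta method. The comparisons, the gene lists, the rule for naming genes and most alternatives were set before the data were examined. The 22 lists covered androgen-regulated genes, luminal and epithelial identity, basal epithelial markers, fibroblast markers, contractile and myofibroblast genes, mesenchymal transition, matrix remodelling, secreted stromal growth factors, neuroendocrine markers, hypoxia and glycolysis, proliferation, inflammatory cytokines and NF-kB targets, interferon-stimulated genes, TGF-beta response, cholesterol and fatty acid synthesis, the unfolded protein response, p53 targets and cell cycle inhibitors, stem cell associated genes, endothelial markers, blood and immune markers, mitochondrially encoded transcripts, and immediate early and heat shock genes. A measured member had at least 1 CPM in 1 of the 2 libraries compared. Each list's median log2 fold was set beside the 95% range of 10000 random lists of its size, drawn from 20 bins of mean expression, which describes these libraries and tests no condition. Medians were computed again with genes at 0 in 1 library set at their bound, and a separate value is printed where it differed at 2 decimals. Of the 31 fibroblast markers in the table, 18 reached 1 CPM in at least 1 monoculture, so the cancer lines expressed part of this list themselves.

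Named genes came from this rule: a set of marker genes for LNCaP, PC-3 and fibroblasts; per comparison, the 10 highest and 10 lowest log2 folds among genes with at least 100 counts and 5 CPM in the higher library; per coculture comparison, the 5 highest and 5 lowest of these with at least 20 CPM in the monoculture; the 2 highest and 2 lowest measured members of each list; and the 10 largest differences between the lines in each direction at 20 CPM or more in all libraries. Sex-linked marker genes, pseudogenes, small noncoding RNA genes and symbols that are only locus or clone names were left out. The rule gave 265 genes, and a gene named outside it is said to have been chosen after its values were seen.

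Alternatives were total counts, DESeq2 1.42.0 size factors, upper-quartile factors, leaving out 38 abundant genes (the 20 highest of any library) before TMM, other low-count filters, a prior count of 0.5, counting-interval limits, and lists without fibroblast markers. Chosen after the data were seen were ribosomal RNA genes left out before TMM, corrections for transcript length alone or with GC content, a minimum of 20 CPM in the monoculture, genes shared by the lines counted at 1 CPM or more in both monocultures, and lists compared between the cocultures on the members measured in the monocultures. Transcript length was that of the shortest principal transcript in GENCODE 29, known for 16635 genes (93.5%). Where a gene had no principal transcript, the shortest basic one was used, which can understate its length. The noncoding gene MALAT1 was set at 234 nt, far below its span on the chromosome. Such genes counted as short in the length bins and corrections. The calls were tried on simulated counts that held counting error alone. In 20 draws from 2 libraries with no difference, the most genes called at least 2-fold in either direction was 62. The 95% intervals held the true ratio in 95.2% to 95.6% of cases, which follows from how they were built and checks the computation only. None of these values covers spread between tissues or libraries. Of 200 genes set to differ, 97% or more were recovered at 3-fold and at 4-fold. Sequence variants, splicing and single transcripts were not analysed here, because the table holds gene totals.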

Results

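RNA from engineered prostate cancer tissues, in which human cancer cells grew inside a poly(ethylene glycol)-fibrinogen hydrogel, was sequenced at day 15 of culture. The 4 libraries formed 4 groups of 1: PC-3 cells alone, LNCaP cells alone, PC-3 cells with BJ-5ta fibroblasts and LNCaP cells with BJ-5ta fibroblasts. PC-3 is a prostate cancer line that the submitters labelled castration-resistant (CRPC-ne in the sample titles, which do not explain the suffix), LNCaP a prostate cancer line that they labelled androgen-dependent, and BJ-5ta an immortalised line of normal human fibroblasts. The cocultures held 5 cancer cells to 1 fibroblast at seeding. The question set by the series is what adding fibroblasts at a set ratio does in tissues of either kind of cancer line. Estimated read counts summed to 15865690 in the PC-3 monoculture, 15860981 in the LNCaP monoculture, 15687894 in the PC-3 coculture and 15520243 in the LNCaP coculture. There were no replicates, so each difference compares 2 libraries rather than 2 conditions, and every interval and floor given for a gene covers counting error only. Gene positions are RefSeq positions on GRCh38.p14, counted from 1.

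Some of the marker genes set beforehand followed the labels of the cell lines, and others did not. KLK3, which encodes prostate-specific antigen (chromosome 19, 50854915 to 50860764), had 60226 counts in the LNCaP monoculture, 74134 in the LNCaP coculture and 0 in either PC-3 library. CD44, a cell surface receptor for hyaluronan (chromosome 11, 35139171 to 35232402), had 2649 counts in the PC-3 monoculture and 1 in the LNCaP monoculture. COL1A2, a chain of type I collagen (chromosome 7, 94394895 to 94431227), had 1 count in the PC-3 monoculture and 0 in the LNCaP monoculture, against 2026 and 3577 in the cocultures. HOXB13, a prostate homeobox gene, had 10668 counts in the PC-3 and 10000 in the LNCaP monoculture and so did not separate the lines. COL1A1, the other chain of type I collagen, was higher in either coculture but already had 3104 and 425 counts in the monocultures of PC-3 and LNCaP, and so was not specific to libraries with fibroblasts.

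**Figure D1:**
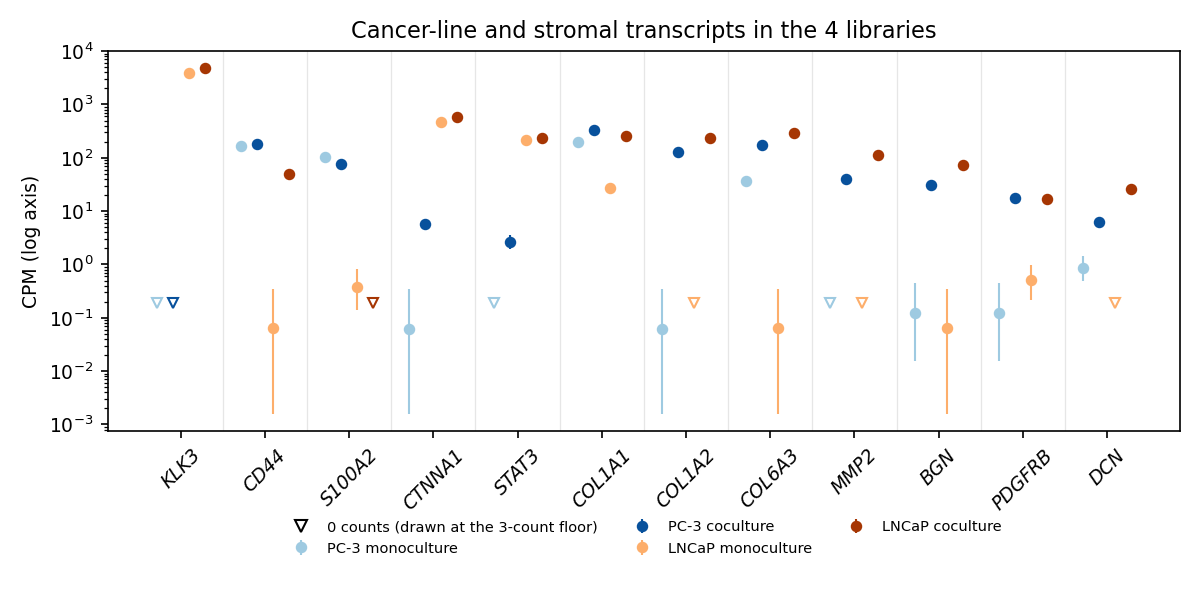
Normalised counts (CPM, counts per 1000000 counts, log axis) of 12 marker and matrix genes in the 4 libraries, with bars for 95% counting intervals and open triangles for genes at 0 counts, drawn at the 3-count floor. KLK3 stood at 0 in both PC-3 libraries, and COL1A2 and MMP2 at 0 or 1 count in both monocultures and at 617 counts or more in both cocultures.

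The PC-3 coculture was compared with the PC-3 monoculture to see what differed when fibroblasts were included with the castration-resistant line. Fibroblast markers and matrix remodelling genes were higher as lists in the coculture, and most genes that the PC-3 monoculture expressed stayed within 2-fold. COL1A2 was 2064-fold higher (2026 against 1 count, 95% counting interval 370 to 81556). TIMP3, an inhibitor of matrix metalloproteinases (chromosome 22, 32801705 to 32863041), had 772 counts against 0 and was at least 262-fold higher, and MMP2, a gelatinase (chromosome 16, 55478830 to 55506691), had 617 against 0 and was at least 210-fold higher. The highest and lowest genes named for each comparison were taken among those with at least 100 counts and 5 CPM in the higher library. The lowest gene by this rule was CBS, an enzyme that makes cystathionine from homocysteine (chromosome 21, 43053191 to 43076873), with 54 counts against 143 and a log2 fold of -1.35, which is 2.60-fold lower (1.89 to 3.62).

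The other genes among the 10 highest by the same rule rested on 2 counts or fewer in the monoculture. The proteoglycan gene BGN was 243-fold higher (66.9 to 2012) from 2 counts, and PDGFRB, a platelet-derived growth factor receptor of mesenchymal cells, 141-fold higher (38.5 to 1167) from 2 counts. At 0 counts in the monoculture were CD248, at least 102-fold higher, CAVIN1, at least 85.9-fold higher, DKK3, at least 66.9-fold higher, AEBP1, at least 49.6-fold higher, and MXRA5, at least 44.5-fold higher. Among genes that the monoculture held at 20 CPM or more, the highest were COL6A3, a chain of type VI collagen (4.70-fold, 4.30 to 5.15), COL3A1, type III collagen (2.55-fold, 2.33 to 2.78), the collagenase gene MMP1 (2.42-fold, 2.15 to 2.72), TNC, the matrix protein tenascin C (2.38-fold, 2.16 to 2.63), and TALAM1, transcribed antisense to MALAT1 (2.07-fold, 1.86 to 2.31). Lower genes were fewer and their differences smaller. BIK, which encodes a pro-apoptotic protein, was 2.10-fold lower (1.52 to 2.94), SPNS2, a sphingosine-1-phosphate transporter, 2.06-fold lower (1.76 to 2.43), and the 10 lowest genes by that rule, which also included FAM229B, TAGLN3, WDR72, GNAZ, ARMCX5-GPRASP2 and BEND5, had log2 folds of -1.35 to -0.92.

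Of 14417 genes with at least 1 CPM in 1 of the 2 libraries, 320 were at least 2-fold higher in the PC-3 coculture and 146 at least 2-fold lower, and 100 of the higher genes had 3 counts or fewer in the monoculture. Libraries simulated with counting error alone, and so without any spread between tissues or libraries, gave a mean of 23.6 higher and 23 lower genes at the same 1 CPM filter, among a mean of 14311 genes. Among the 8579 genes at 20 CPM or more in the monoculture, 19 were at least 2-fold higher and 1, SPNS2, at least 2-fold lower. The counts depended on the low-count filter: 906 genes were higher and 440 lower with none, and 87 and 21 at 5 CPM or more.

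Fibroblast markers had the highest median of the measured lists in the PC-3 coculture. Of 29 measured fibroblast markers, 15 were at least 2-fold higher, 0 lower and 14 in between, with a median log2 fold of 1.35 where random lists of like expression spanned -0.12 to 0.14. COL1A1, which the PC-3 monoculture already held at 3104 counts, was 1.68-fold higher (1.61 to 1.76), and DCN, the small proteoglycan decorin, was 7.13-fold higher (4.05 to 13.5). Of 13 contractile and myofibroblast genes, 6 were at least 2-fold higher and 0 lower (median 0.34), among them ITGA11, a collagen-binding integrin (77 counts against 0, at least 26.1-fold), and ACTA2, smooth muscle actin (31.6-fold, 5.26 to 1287, from 1 count). Of 29 matrix remodelling enzymes and inhibitors, 5 were at least 2-fold higher and 0 lower (median 0.23), led by TIMP3 and MMP2, while LOXL4, a lysyl oxidase, had a fold of 0.647.

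Mesenchymal transition genes were split in the PC-3 coculture. Of 20 measured, 5 were at least 2-fold higher and 0 lower, with a median log2 fold of 0.06 inside the random range of -0.13 to 0.14. The higher members included TGFBI, a matrix protein gene (144-fold, 25.4 to 5713, from 1 count), and TWIST2, a mesenchymal transcription factor (16.2-fold, 7.58 to 41.1). Members that the PC-3 monoculture already expressed were split too. FN1, fibronectin, had a fold of 1.00 (0.964 to 1.04) and VIM, the intermediate filament vimentin, of 0.823 (0.802 to 0.845). TNC, which the monoculture held at 20 CPM or more, was at least 2-fold higher, as given above. Of 22 secreted stromal growth factors, 4 were at least 2-fold higher and 0 lower, and their median of -0.01 and mean of 0.54 differed in sign. Among them, IGFBP7 was 60.1-fold higher (25.5 to 186) and HGF, the ligand of the MET receptor, 4.84-fold higher. Of 20 TGF-beta response genes, 1, TGFBI, was at least 2-fold higher and 0 lower, and the median of -0.01 and mean of 0.28 again differed in sign. ID3, a BMP and TGF-beta responsive inhibitor of differentiation, was lower (fold 0.586, 0.472 to 0.727), and THBS1, thrombospondin, was higher (1.66-fold, 1.55 to 1.78).

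Interferon-stimulated genes were higher in the PC-3 coculture with small folds. Of 26 measured, 24 had a log2 fold above 0 and 1, the chemokine gene CXCL10, was at least 2-fold higher (17 counts against 2, 8.66-fold, 2.06 to 77.3), with a list median of 0.42 against a random range of -0.10 to 0.11. OAS2, an antiviral sensor of double-stranded RNA (chromosome 12, 112978519 to 113011723), was 1.50-fold higher (12181 against 8285 counts, 1.46 to 1.54), and MX2, an antiviral GTPase, 1.84-fold higher (1.69 to 2.00). IFI27 (fold 0.936, 0.860 to 1.02) and ISG20 (fold 0.905, 0.801 to 1.02) were the members below 0. Of 22 inflammatory cytokines and NF-kB targets, 5 were at least 2-fold higher and 0 lower (median 0.26), among them the chemokine gene CCL2 (18.8-fold, 4.86 to 161, from 2 counts) and PTGS2, cyclooxygenase 2 (3.30-fold, 2.31 to 4.81). The fibroblast markers were higher in the same library, by a median of 1.35.

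Proliferation genes were also higher in the PC-3 coculture by small folds. Of 30 measured, 26 had a log2 fold above 0 and 0 reached 2-fold in either direction, with a median of 0.21 against a random range of -0.09 to 0.09. CENPF, a kinetochore protein (chromosome 1, 214603195 to 214664571), was 1.67-fold higher (1424 against 870 counts, 1.53 to 1.82) and MKI67, the Ki-67 antigen, 1.54-fold higher (1.44 to 1.65), whereas the replication clamp gene PCNA (fold 0.956, 0.902 to 1.01) and the kinase gene AURKB (fold 0.984) were not. After correction for transcript length, the list median was 0.19. Hypoxia and glycolysis genes were lower as a list, with a median of -0.17 below the random range of -0.09 to 0.11 and a mean of -0.03. Among its 28 members, 7 had a log2 fold above 0, 2 were at least 2-fold higher and 0 lower. The glucose metabolism regulator PFKFB3 (fold 0.733, 0.697 to 0.770) and the stress gene NDRG1 (fold 0.804, 0.797 to 0.812) were lower. The carbonic anhydrase gene CA9 (2.59-fold, 1.75 to 3.90) and the glucose transporter gene SLC2A3 (13.0-fold, 4.77 to 49.5) were higher.

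Luminal and epithelial identity genes were slightly higher as a list in the PC-3 coculture. Of 23 measured, 18 had a log2 fold above 0 and 0 reached 2-fold (median 0.15, random range -0.10 to 0.12). The median was 0.18 after correction for transcript length. CDH1, E-cadherin, was 1.20-fold higher (1.16 to 1.24) and the prostate homeobox gene HOXB13 had a fold of 0.826 (0.803 to 0.850). Of 21 androgen-regulated genes (median -0.07) and 10 basal epithelial markers (median 0.07), 0 reached 2-fold. Among the basal markers, S100A2 had a fold of 0.726 (0.674 to 0.782). Of 13 neuroendocrine markers, 2 were at least 2-fold higher and 0 lower (median 0.16): UCHL1, a ubiquitin hydrolase (77.4-fold, 13.5 to 3098, from 1 count), and SCG2, a secretogranin (2.65-fold). UCHL1 was higher in the LNCaP coculture too, and whether fibroblasts or PC-3 cells held it was not tested. The synaptic vesicle gene SYP was lower (29 against 52 counts, fold 0.568, 0.348 to 0.912).

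The LNCaP coculture was compared with the LNCaP monoculture to see what differed when fibroblasts were included with the androgen-dependent line. Fibroblast markers again had the highest median of the measured lists, followed here by mesenchymal transition genes. COL1A2 had 3577 counts against 0 and was at least 1214-fold higher, and COL6A3 (chromosome 2, 237324018 to 237414164) had 4449 against 1 and was 4529-fold higher (812 to 178930). MMP2 had 1779 counts against 0 (at least 604-fold), and CD44 776 against 1 (790-fold, 141 to 31242). Genes encoding ribosomal proteins were among the lowest, with RPL39 (chromosome X, 119786504 to 119791630) at 599 counts against 2254 and a log2 fold of -1.88, which is 3.70-fold lower (3.38 to 4.05). KLK3, the androgen-regulated marker of the line, was 1.25-fold higher (1.24 to 1.27).

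The rest of the 10 highest genes in the LNCaP coculture were BGN (1135-fold, 203 to 44873, from 1 count), LUM, the proteoglycan lumican (at least 196-fold), the gap junction gene GJA1 (at least 190-fold), the collagen receptor gene MRC2 (at least 188-fold), TIMP3 (353-fold, 120 to 1714, from 3 counts) and DCN (at least 135-fold). Among genes at 20 CPM or more in the monoculture, COL1A1 (chromosome 17, 50184101 to 50201631) was 9.45-fold higher (3946 against 425 counts, 8.55 to 10.5). VIM was 3.42-fold higher (3.23 to 3.62), COL6A2 3.41-fold higher (3.23 to 3.61), TNFRSF19, a receptor of the tumour necrosis factor family, 2.24-fold higher (2.04 to 2.47), and TRPS1, a transcriptional repressor, 2.23-fold higher (2.02 to 2.47). Lower genes included ID3 (3.48-fold lower, 3.02 to 4.02), the adrenergic receptor gene ADRA2A (3.46-fold lower, 3.22 to 3.72), PRAC2 (3.41-fold lower, 2.78 to 4.20) and the ribosomal protein genes RPS21 (3.31-fold lower, 3.14 to 3.49) and RPS29 (3.11-fold lower, 2.91 to 3.32). Also among the 10 lowest were MYOD1 and TEN1-CDK3, PCDHGA6 and RBM14-RBM4, which overlap or closely resemble other genes.

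Of 14119 genes with at least 1 CPM in 1 of the 2 LNCaP libraries, 644 were at least 2-fold higher in the coculture and 428 at least 2-fold lower. Of the higher genes, 251 had 3 counts or fewer in the monoculture, and 22 of the lower genes had 3 or fewer in the coculture. Libraries simulated with counting error alone, which hold no spread between tissues or libraries, gave a mean of 24.2 higher and 21.8 lower genes at the same 1 CPM filter, among a mean of 13920 genes. Among the 8481 genes at 20 CPM or more in the monoculture, 12 were at least 2-fold higher and 69 lower. The higher and lower counts were 1286 and 753 with no low-count filter and 240 and 154 at 5 CPM or more, and the lower count was 278 after correction for transcript length and GC content.

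Fibroblast markers were higher almost throughout in the LNCaP coculture. Of 30 measured, 27 were at least 2-fold higher and 0 lower, with a median log2 fold of 4.84, or 4.60 with genes at 0 counts set at their bound, against a random range of -0.26 to 0.20. PDGFRB was 33.7-fold higher (16.9 to 78.9). The members outside this pattern were TWIST1 (fold 0.787), COL5A2 (fold 0.958) and COL6A1 (1.24-fold), the last singled out after its value was seen. Of 12 contractile and myofibroblast genes, 4 were at least 2-fold higher and 0 lower (median 0.64), including TPM2, a tropomyosin (13.1-fold, 7.88 to 23.4), and ITGA11 (6.49-fold).

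Mesenchymal, matrix and growth factor lists were higher in the LNCaP coculture together with these fibroblast markers. Of 19 mesenchymal transition genes, 14 were at least 2-fold higher and 0 lower, with a median of 4.34 (3.96 with genes at 0 set at their bound). CD44 and VIM were among them, as was MMP14, a membrane-bound metalloproteinase (576-fold, 103 to 22798, from 1 count), and FN1 was 1.46-fold higher (1.43 to 1.49). Of 29 matrix remodelling genes, 20 were at least 2-fold higher and 0 lower (median 2.17), including MMP1 (220 counts against 0, at least 74.7-fold). Of 20 secreted stromal growth factors, 14 were at least 2-fold higher and 0 lower (median 3.22), among them GREM1, a BMP antagonist (at least 56.0-fold), and IGFBP5 (70.0-fold, 45.6 to 114). Of 19 TGF-beta response genes, 7 were at least 2-fold higher and 1, ID3, at least 2-fold lower (median 0.27, random range -0.23 to 0.21).

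Proliferation genes were lower in the LNCaP coculture. Of 30 measured, 2 had a log2 fold above 0, the replication licensing genes MCM3 (1.09-fold) and MCM4 (1.02-fold), and the median was -0.31 against a random range of -0.09 to 0.13. CCNE2, cyclin E2, was the member lower by more than 2-fold (75 against 177 counts, 2.32-fold lower, 1.76 to 3.08). UBE2C, a mitotic ubiquitin-conjugating enzyme, had a fold of 0.544 (0.469 to 0.631), CENPF of 0.757 (0.709 to 0.808) and MKI67 of 0.800 (0.747 to 0.858). The list median was -0.34 after correction for transcript length. In the same library the median was 4.84 for fibroblast markers and -0.73 for ribosomal protein genes.

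Interferon-stimulated genes in the LNCaP coculture were higher from low starting counts. All 23 measured members had a log2 fold above 0, and 10 were at least 2-fold higher, with a median of 0.87 against a random range of -0.29 to 0.22. OAS2 had 46 counts against 0 (at least 15.6-fold), XAF1 22 against 0 (at least 7.47-fold) and MX2 34 against 2 (17.3-fold, 4.44 to 149), while OAS3 (1.02-fold) and ISG15 (1.09-fold, 0.966 to 1.22) were close to their monoculture levels. Of 12 inflammatory cytokines and NF-kB targets, 3 were at least 2-fold higher and 0 lower (median 0.57), including PTGS2 (44 against 2 counts, 22.4-fold, 5.84 to 191) and IL1B, interleukin 1 beta (5.77-fold). In the same library the fibroblast markers were higher by a median of 4.84.

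Androgen-regulated genes were slightly higher in the LNCaP coculture as a list, and luminal genes stayed within 2-fold. Of 26 members, 1, STEAP4, a metalloreductase, was at least 2-fold higher (29 against 8 counts, 3.69-fold, 1.65 to 9.34) and 0 lower, with a median of 0.20 above the random range of -0.10 to 0.16; after correction for transcript length it was 0.12, at percentile 89.4 of random lists. ABCC4, an organic anion and prostaglandin exporter, was 1.69-fold higher (1.64 to 1.75) and TMPRSS2, a serine protease, 1.34-fold higher (1.32 to 1.36), whereas KLK2, a kallikrein, had a fold of 0.903 (0.875 to 0.932). Of 22 luminal and epithelial identity genes, 0 reached 2-fold (median 0.13); CDH1 was 1.37-fold higher (1.34 to 1.41) and the keratin gene KRT19 had a fold of 0.647. Of 7 basal epithelial markers, 1, CD44, was at least 2-fold higher and 0 lower (median 0.14). Of 10 neuroendocrine markers, 1 was at least 2-fold higher and 1 lower, and the median of -0.12 and mean of 0.18 differed in sign; UCHL1 was 15.4-fold higher and the somatostatin receptor gene SSTR2 had a fold of 0.359. Of 28 hypoxia and glycolysis genes, 4 were at least 2-fold higher and 0 lower, and the median of -0.09 and mean of 0.26 also differed in sign. CA9 (15.8-fold, 8.11 to 35.4) and ADM, the vasodilator peptide adrenomedullin (8.47-fold, 5.43 to 13.8), were higher, while PFKFB3 (fold 0.650, 0.623 to 0.678) and ANKRD37 (fold 0.560, 0.519 to 0.604) were lower.

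**Figure D2:**
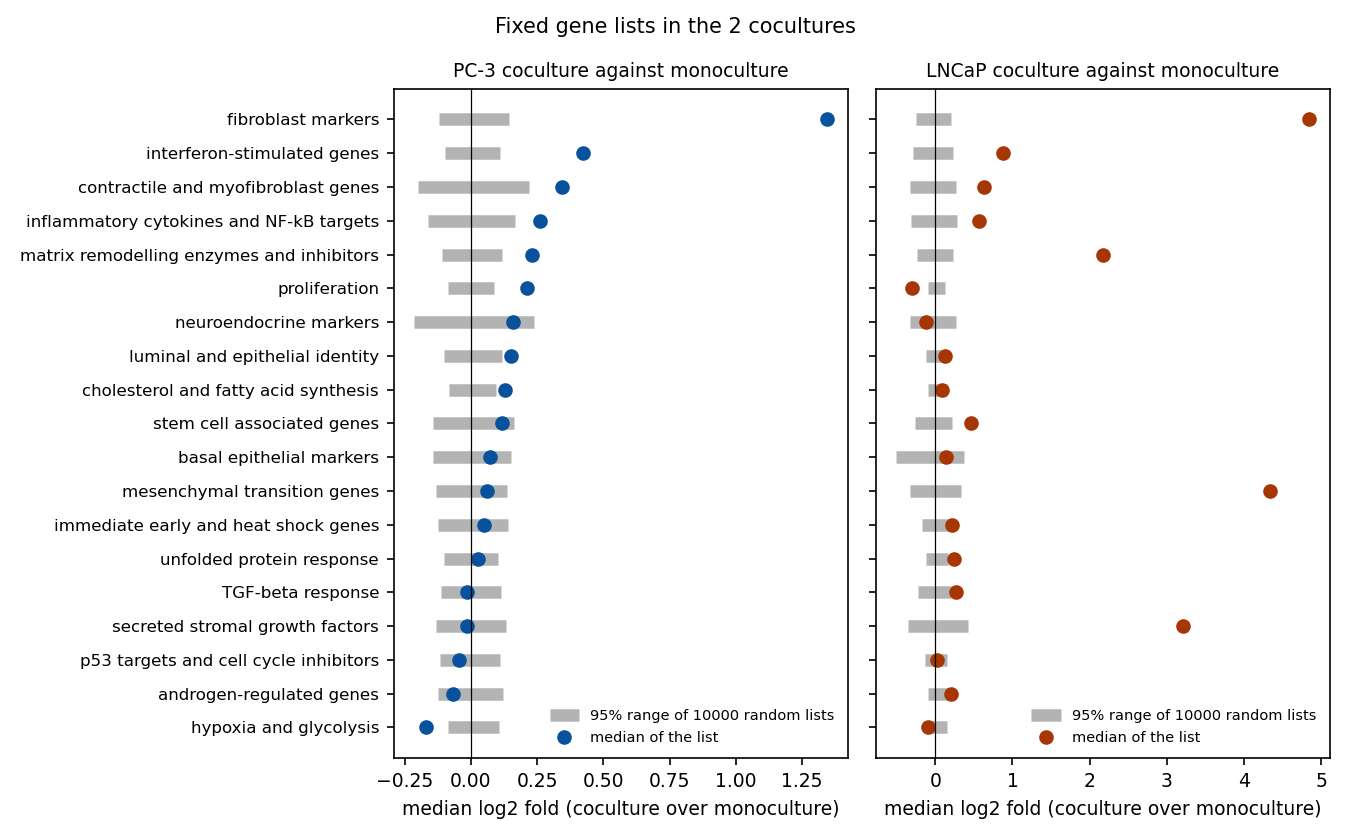
Median log2 fold of 19 fixed gene lists in each coculture against its monoculture, with a panel per cell line on its own scale; points are list medians and grey bars the 95% range of 10000 random lists of like size and expression. Fibroblast markers lay at 1.35 in PC-3 and 4.84 in LNCaP, and proliferation genes at 0.21 and -0.31.

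Ribosomal protein genes, and short transcripts in general, were lower in both cocultures. Of 75 ribosomal protein genes at 20 CPM or more in the PC-3 monoculture, 74 had a log2 fold below 0 and 0 were at least 2-fold lower, with a median of -0.45. Of 79 in LNCaP, 77 were below 0 and 21 at least 2-fold lower, with a median of -0.73. Other genes with transcripts under 600 nt had a median of -0.29 in PC-3 and -0.40 in LNCaP, against 0.03 and 0.06 for transcripts of 3000 to 5000 nt. Of 66 genes at 20 CPM or more that had a transcript length and were at least 2-fold lower in the LNCaP coculture, 49 had transcripts under 1000 nt.

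**Figure D3:**
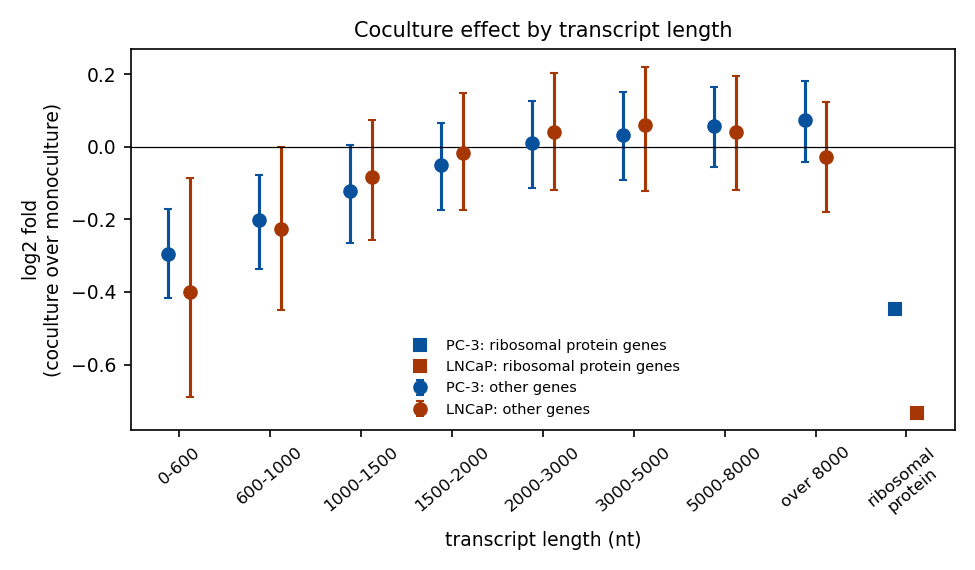
Median log2 fold (points) and quartiles (bars) of genes at 20 CPM or more in the monoculture, other than ribosomal protein genes, in 8 bins of transcript length (nt), for each coculture against its monoculture; squares mark the ribosomal protein genes. Medians were lowest under 600 nt, at -0.29 in PC-3 and -0.40 in LNCaP, and the squares stood lower still, at -0.45 and -0.73.

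Whether the lines differed alike between coculture and monoculture was asked gene by gene, from comparisons that shared no library. Fibroblast markers were higher as a list in both lines, with the higher median in LNCaP, and proliferation and ribosomal protein genes had lower medians in LNCaP than in PC-3. Single genes could differ the other way, as did CAVIN1, among the 10 highest in the PC-3 coculture, with a log2 fold in LNCaP minus that in PC-3 of -5.69 (-7.71 to -3.67). CAVIN1 was undetected in the PC-3 monoculture but lay above the 3-count floor in the LNCaP monoculture, so its starting level differed between the lines. Among genes at 20 CPM or more in all 4 libraries, COL1A1 had the largest difference, with its log2 fold 2.49 higher in LNCaP (95% counting interval 2.33 to 2.64), followed by VIM (2.05, 1.96 to 2.14; chromosome 10, 17228241 to 17237593) and COL6A2 (1.43, 1.34 to 1.52). At the other end were the nuclear noncoding RNA genes TALAM1 (chromosome 11, 65499312 to 65507432), with a difference of -1.74 (-1.91 to -1.56), and MALAT1 (chromosome 11, 65497738 to 65506516), with -1.57 (-1.64 to -1.51), which overlap each other on the chromosome. MALAT1 had 6154 counts against 3109 in the PC-3 coculture and monoculture, and 15419 against 23202 in the LNCaP libraries. A log2 fold depends on the monoculture level, because the same added counts give a larger fold from a lower start. COL1A1, VIM and fibroblast markers as a list had lower monoculture levels in LNCaP than in PC-3. How much of their differences between the lines came from the starting level was not tested.

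The remaining genes higher in LNCaP relative to PC-3 were TRPS1, LDOC1, TP53INP2, KLHL5, the metallothionein gene MT2A, IGFBP3 and PLAAT3, with differences of 1.07 down to 0.95. Those on the PC-3 side included RAD54B, a recombination gene (-1.29, -1.55 to -1.02), LAMA3, a laminin chain (-1.25, -1.44 to -1.07), RPS21 (-1.25, -1.37 to -1.14), the kinetochore gene KNL1 (-1.21), RPL39 (-1.19), IQGAP3 (-1.17) and PPFIA4 (-1.17). LAMA3 had a fold of 1.36 (1.30 to 1.43) in PC-3 and 0.569 (0.505 to 0.641) in LNCaP. The proliferation genes CENPF (-1.14, -1.29 to -0.98) and MKI67 (-0.94, -1.08 to -0.80) also lay on the PC-3 side.

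Genes at least 2-fold higher were counted in both lines together. Among 13005 genes counted in both comparisons, 237 were higher in the PC-3 coculture, 541 in the LNCaP coculture and 121 in both, where 9.86 would be shared if the sets were independent. Genes silent in both monocultures pass the filter only if both cocultures hold them, which favours sharing. Among the 12403 genes at 1 CPM or more in both monocultures, a set chosen for this count after the values were seen, 57 were higher in the PC-3 coculture, 160 in the LNCaP coculture and 14 in both, against 0.735 under independence. Lower genes among the 13005 numbered 86 and 283, with 10 shared and 1.87 under independence. Across 15531 genes, which are not independent replicates, the log2 folds of the lines correlated with Pearson's r of 0.325 and Spearman's rho of 0.168. Across the 12403 genes at 1 CPM or more in both monocultures, Pearson's r was 0.220 and Spearman's rho 0.201, and the whole comparison rests on 1 library per group. Both cocultures were seeded with BJ-5ta fibroblasts, which favours sharing of higher genes, and short transcripts were lower in both. Shared genes above independence, or a correlation, therefore do not show that the cancer cells of the lines responded alike.

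The monocultures of the lines were compared to give their difference without fibroblasts. Kallikreins and other androgen-regulated genes were higher in LNCaP, and interferon-stimulated, basal, mesenchymal and matrix genes were higher in PC-3. KLK3 stood at 60226 counts against 0, at least 20294-fold higher in LNCaP, and KLK2 at 8461 against 0, at least 2851-fold higher. CTNNA1, alpha-catenin, which links cadherins to actin (chromosome 5, 138753425 to 138935034), had 7288 counts in LNCaP and 1 in PC-3 (7367-fold higher, 1322 to 291040), and STAT3, a cytokine-activated transcription factor, had 3422 and 0 (at least 1153-fold higher). In the other direction, MSMP, a microseminoprotein gene (chromosome 9, 35752990 to 35754276), had 0 counts in LNCaP and 44821 in PC-3 (at least 14779-fold lower in LNCaP), and the calcium-binding protein gene S100A6 0 and 29652 (at least 9777-fold lower).

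Further genes among the 10 highest in LNCaP were KLK4, SYT4, PPFIA2, SPON2 (2262-fold, 1230 to 4718), MME, the membrane protease neprilysin, and ADRA2A (at least 1144-fold). Further genes among the 10 lowest were the Wnt inhibitor gene DKK1 (at least 4925-fold lower), the keratin genes KRT7 (at least 3555-fold lower) and KRT81 (7130-fold lower, 1973 to 58883, from 2 counts in LNCaP), SPTSSB, OAS2 (at least 2732-fold lower), the cartilage collagen gene COL2A1 (at least 2341-fold lower), PLAU, urokinase (at least 1892-fold lower), and LGALS3, galectin 3. Of 15160 genes counted, 3354 were at least 2-fold higher in LNCaP and 3578 at least 2-fold lower.

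Androgen-regulated genes had a median log2 fold of 2.34 in the LNCaP monoculture against PC-3, with 17 of 26 at least 2-fold higher and 5 lower. The prostate homeobox gene HOXB13 had a fold of 0.948. Interferon-stimulated genes were lower, with 23 of 25 at least 2-fold lower and 0 higher (median -5.19). Basal epithelial markers (median -6.62, 1 of 11 higher and 10 lower), mesenchymal transition genes (median -6.05, 2 of 17 higher and 14 lower), matrix remodelling genes (median -4.66, 6 of 25 higher and 16 lower) and fibroblast markers (median -4.10, 2 of 18 higher and 15 lower) were lower too. VIM was 8.16-fold lower (7.74 to 8.61) and COL1A1 7.22-fold lower (6.53 to 8.01) in LNCaP, but FN1 was 2.72-fold higher (2.64 to 2.81). Secreted stromal growth factors had a median of -4.89 (-4.26 with genes at 0 set at their bound; 1 of 19 higher and 17 lower), inflammatory genes of -3.15 (-2.79 at their bound; 1 of 19 higher and 14 lower) and TGF-beta response genes of -2.07 (3 of 19 higher and 13 lower). Proliferation genes were modestly higher, with 24 of 30 above 0, 7 at least 2-fold higher and a median of 0.49. Hypoxia and glycolysis genes (11 of 28 higher and 6 lower) had a median of 0.62 and a mean of -0.07, which differ in sign. Neuroendocrine markers had a median of -0.47 inside the random range of -1.44 to 1.17 (3 of 13 higher and 5 lower), with SYT4 the highest in LNCaP and FOXA2 the lowest.

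The cocultures of the lines were compared to give their difference with fibroblasts included. Some genes that set the lines apart alone did so here too, while gaps in several lists were narrower or absent. Part of the narrowing came from members measured only in the cocultures. Over the members measured in the monocultures, sets chosen after the values were seen, the median log2 fold of LNCaP against PC-3 was -4.10 in the monocultures and -0.92 in the cocultures for 18 fibroblast markers, -6.05 and -1.78 for 17 mesenchymal transition genes, and -4.66 and -2.09 for 25 matrix remodelling genes. KLK3 was at least 24964-fold higher in LNCaP (74134 against 0 counts), and MSMP had 0 counts against 33236. CTNNA1 stood at 8977 counts in the LNCaP coculture and 90 in the PC-3 coculture (101-fold higher, 81.9 to 125), and STAT3 at 3689 and 42 (88.7-fold higher, 65.5 to 123). S100A6 had 156 counts in the LNCaP coculture and was 142-fold lower there (121 to 167), and CD44 was 3.59-fold lower (3.32 to 3.90).

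Also among the 10 highest in the LNCaP coculture were SYT4, KLK2 (at least 2528-fold), TMEFF2, KLK4, PPFIA2 (at least 1311-fold), the neural adhesion gene NCAM2 (1864-fold, 1090 to 3502), PRUNE2, SPON2 and ZBTB16 (at least 946-fold). Among the 10 lowest were KRT81, COL2A1 (at least 2471-fold lower), ADGRF1 (at least 2004-fold lower), TMEM30B (at least 1807-fold lower), KRT7, S100A14, KCNK15 (at least 1136-fold lower), CEACAM5, a carcinoembryonic antigen family gene, and SPTSSB. Of 15155 genes counted, 3130 were at least 2-fold higher in LNCaP and 3579 at least 2-fold lower.

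Over all measured members, fibroblast markers were close to balance between the cocultures, with 7 of 30 at least 2-fold higher in LNCaP, 9 lower and a median of -0.25 inside the random range of -0.45 to 0.50. COL1A2 was 1.78-fold higher in LNCaP (1.69 to 1.88), MMP2 2.91-fold higher (2.66 to 3.20) and DCN 4.11-fold higher (3.29 to 5.18), and PDGFRB had a fold of 0.970 (0.816 to 1.15). Mesenchymal transition genes had a median of -0.93 (1 of 20 higher and 9 lower) and matrix remodelling genes of -0.65 (9 of 30 higher and 14 lower), with VIM 1.96-fold lower in LNCaP (1.90 to 2.03). Androgen-regulated genes had a positive median of 2.51 (18 of 26 higher and 4 lower), and interferon-stimulated genes a negative median of -4.82 (0 of 26 higher and 24 lower), with OAS2 at 46 against 12181 counts. Basal epithelial markers had a median of -5.55 (1 of 11 higher and 10 lower). For proliferation genes the median was -0.02, with 13 of 30 above 0, 0 at least 2-fold higher and 1 lower. Hypoxia and glycolysis genes had a median of 0.76 (11 of 28 higher and 5 lower), above the random range of -0.39 to 0.53. Neuroendocrine markers had a median of -0.53 inside the random range of -1.32 to 0.97 (3 of 14 higher and 6 lower).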

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

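The median of proliferation genes had opposite signs in the lines. Their median log2 fold in coculture against monoculture was 0.21 in PC-3 and -0.31 in LNCaP. In PC-3, 26 of 30 members were above 0, and in LNCaP 28 of 30 were below 0. Each value compares 1 library with 1 other, and the difference between the lines was not tested. The transcript length correction, chosen after these values were seen, left the medians at 0.19 and -0.34. Other features of the libraries differed alongside: fibroblast markers had medians of 1.35 in PC-3 and 4.84 in LNCaP, and ribosomal RNA genes took 0.751% of counts in the PC-3 monoculture and 2.16% in its coculture, against 1.46% and 1.23% in LNCaP. The fibroblast marker medians depend on the monocultures too. Over 18 of these markers, LNCaP against PC-3 had a median log2 fold of -4.10 in the monocultures and -0.92 in the cocultures. Over all 30 measured in the cocultures it was -0.25. The medians of 1.35 and 4.84 therefore do not give the amount of fibroblast RNA in either coculture.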

How the results depend on the processing

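The alternatives chosen only after the results were seen were the 20 CPM minimum, the length and GC corrections, the 1 CPM minimum in both monocultures for shared genes, the lists on members measured in the monocultures and the removal of ribosomal RNA genes before TMM. The counts of genes at least 2-fold apart depended on which genes were counted, as each filter admits fewer or more genes near the floor. In PC-3, 906 genes were higher and 440 lower with no filter, 87 and 21 at 5 CPM or more in 1 library, and 19 and 1 at 20 CPM or more in the monoculture; 95 were higher at 1 CPM or more in the monoculture. In LNCaP these counts were 1286 and 753, 240 and 154, and 12 and 69, and 188 were higher at 1 CPM or more in the monoculture. The LNCaP lower count was 278 after length and GC correction, and the cause was not tested. Under each of the scalings, the prior count of 0.5 and the counting-interval limit, all 8 counts stayed within 1.5 times, as did all 4 counts between the lines in every setting run. The correlation of the coculture differences, 0.325 in the main setting, was 0.220 at 1 CPM or more in both monocultures, 0.295 with a prior count of 0.5, and at 20 CPM or more in both monocultures 0.333 without and 0.250 with length correction. Spearman's rho, 0.168 in the main setting, was 0.201, 0.165, 0.276 and 0.215 in the same order, and the cause was not tested. Genes at least 2-fold higher in both cocultures numbered 121 in the main setting and 14 at 1 CPM or more in both monocultures, as fewer genes near the floor were counted, and the lower ones 10 in both. Over the members measured in the monocultures, the medians in LNCaP against PC-3 coculture were -0.92 rather than -0.25 for fibroblast markers, -1.78 rather than -0.93 for mesenchymal transition genes and -2.09 rather than -0.65 for matrix remodelling genes, as fewer members were counted, and of 21 list medians 15 stayed within their counting intervals and 6 did not. In the LNCaP coculture, the endothelial median became -0.051 when the most abundant genes were left out before TMM, because 3 members rather than 2 passed the filter, and the blood and immune median became -0.47 with no filter, from 5 genes rather than 1. No other list median outside its random range changed sign. Of 84 list medians, 84 stayed within their counting intervals with total counts, 75 with DESeq2 factors, 80 with upper-quartile factors, 78 with a prior count of 0.5, 56 at 5 CPM or more and 63 with no filter; among those of the cocultures, 38 did and 4 did not after length correction, and 32 did and 10 did not when members needed 1 CPM in the monoculture. With total counts or a prior count of 0.5, all 984 values of named genes stayed within their counting intervals, with DESeq2 factors 947 did, and with upper-quartile factors 970 did. No paired analysis was possible because each group had 1 library. Depth limits folds of genes near 0, which rest on 3 counts or fewer in 1 library.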

Other observations

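Stress-related and metabolic lists not described above are given here. Of 23 unfolded protein response genes, 0 reached 2-fold in either coculture, with a median log2 fold of 0.24 in LNCaP (random range -0.11 to 0.16) and 0.03 in PC-3. In the LNCaP coculture, HSPA5, the chaperone BiP of the endoplasmic reticulum, and HSP90B1, the HSP90 chaperone of the same compartment, were each 1.56-fold higher, while DDIT3, a transcription factor of stress-induced cell death, had a fold of 0.726 (0.652 to 0.809). Cholesterol and fatty acid synthesis genes had medians of 0.13 in PC-3 (random range -0.08 to 0.10) and 0.09 in LNCaP, with 0 of 29 and 0 of 28 at 2-fold; SQLE, squalene epoxidase, was 1.27-fold higher in PC-3. Of 23 p53 targets and cell cycle inhibitors, 0 reached 2-fold in either line (medians -0.05 and 0.02). Immediate early and heat shock genes had medians of 0.05 in PC-3 (3 of 17 at least 2-fold higher and 0 lower) and 0.22 in LNCaP (random range -0.17 to 0.19, 3 of 16 higher and 0 lower), and EGR1, an immediate early transcription factor, was 12.2-fold higher in PC-3 (5.68 to 31.3) and 4.80-fold higher in LNCaP (3.66 to 6.39).

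Among stem cell associated genes, 0 of 11 reached 2-fold in PC-3 (median 0.12), and in LNCaP 2 of 10 were at least 2-fold higher and 1 lower (median 0.47, random range -0.27 to 0.22). CD44 and ITGA2, a collagen-binding integrin (2.62-fold, 2.23 to 3.09), were the higher genes, and POU5F1, a pluripotency factor, the lower (41 against 87 counts, fold 0.480, 0.323 to 0.703). In the same LNCaP coculture the fibroblast markers were higher by a median of 4.84. Of 5 endothelial markers in PC-3, 0 reached 2-fold (median -0.04, mean 0.04, which differ in sign), and of 2 in LNCaP, 1, VWF, was 3.38-fold higher (2.84 to 4.03, list median 0.85). The LNCaP median rests on those 2 members and changed sign when the most abundant genes were left out before TMM. Of 3 blood and immune markers in PC-3, 1, CD14, was at least 2-fold higher (26 against 9 counts, list median 0.47), and the 1 measured in LNCaP, CD68, was 3.72-fold higher (2.83 to 4.95).

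The tests of explanations in the paragraphs that follow were chosen only after the results they measure were seen. A set of 14 genes, chosen after their values were seen, had 3 counts or fewer in both monocultures and 100 or more in a coculture, with summed counts of 5252 in the PC-3 coculture and 9802 in the LNCaP coculture. Reads carried over from the library of the other cancer line are argued against, since at the share of CTNNA1 the PC-3 coculture would hold 743 counts of KLK3, at the share of S100A6 the LNCaP coculture would hold 232 of MSMP, and both were at 0. The 90 counts of CTNNA1 and 42 of STAT3 in the PC-3 coculture, against 1 and 0 in the PC-3 monoculture, fit RNA of cells other than PC-3, for which the seeded fibroblasts are a candidate source. Each gene stood there at 1.24% of its CPM in the LNCaP monoculture, whereas fibroblasts were 16.7% of the cells seeded in the coculture. In the LNCaP coculture, S100A6 stood at 0.541% and LGALS3 at 1.44% of their CPM in the PC-3 monoculture. Such shares thus differed between genes. The level of these genes in fibroblasts was not known, so the share of fibroblast RNA at day 15 could not be told and need not equal the seeded share. Whether 1 fixed fibroblast profile was added to both cocultures could not be told: the log2 ratio of the cocultures over the 14 genes had an SD of 1.25, above the 0.331 that 1000 simulations of counting error reached, and of 0.490 without COL5A3 and MFAP4, but the spread between separate libraries was not known. How much of each stromal or mesenchymal difference came from fibroblasts and how much from cancer cells stays open, since no library held fibroblasts alone. The same holds for UCHL1 among the neuroendocrine markers and for CD44 among the basal and stem cell associated genes.

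Short transcripts, ribosomal protein genes among them, were lower in both cocultures. A trend with transcript length as the whole cause for ribosomal protein genes is argued against, since they lay below the 50 other genes nearest in length by a median log2 fold of -0.22 in PC-3 (95% bootstrap interval -0.27 to -0.19) and -0.47 in LNCaP (-0.62 to -0.39). They also lay below other genes under 600 nt, by -0.15 (-0.20 to -0.08) and -0.33 (-0.53 to -0.22). That second comparison did not match length, as the ribosomal protein genes had median transcript lengths of 705 nt in PC-3 and 709 nt in LNCaP. It therefore does not decide the question alone. A difference of ribosomal protein genes alone is argued against too, since other genes under 1000 nt had medians of -0.22 in PC-3 (539 genes, -0.25 to -0.20) and -0.25 in LNCaP (558 genes, -0.29 to -0.22). The bootstrap intervals resample genes, which are not independent, within 1 pair of libraries per line. They describe these libraries and do not cover spread between libraries. A length trend with a further difference in ribosomal protein genes may therefore be present, and whether RNA integrity, library preparation or the cells present gave rise to either stays open, as the labels give no RNA integrity and each group had 1 library.

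Interferon-stimulated genes were higher in the PC-3 coculture. Transcript length bias is argued against, since the list median after length correction was 0.44 and lay above the 95% range of random lists. Fibroblast RNA with the interferon-stimulated transcripts gained in the LNCaP coculture is argued against as well: the list gained 2213 CPM in the PC-3 coculture and 112 CPM in the LNCaP coculture, which becomes 107 CPM at 0.955, the highest ratio of PC-3 to LNCaP coculture among the 11 of the 14 genes above with at least 100 counts in both cocultures. COL5A3, with 12 counts in the LNCaP coculture, had a higher ratio of 7.96, at which the product would still lie below 2213 CPM. A higher level of these transcripts in the PC-3 cells of the coculture is a hypothesis that the data leave open, as are fibroblasts with more of these transcripts beside PC-3 than beside LNCaP cells and chance differences between single tissues or libraries.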
